A study of Mus musculus with 18 samples.

How the data were processed

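The data are from MuSCs sorted by flow cytometry from hindlimb muscle of WT and Ezh1-/- mice and processed directly, per the labels' protocols. Bulk RNA libraries were poly(A) selected and single-cell libraries used a 10x 3' tag kit with UMIs, per the labels' protocols. The submitters' processing notes name Trim Galore 0.6.6, TopHat2 2.1.1, Bowtie 1.1.1, MACS 1.4.2, Partek 7.18, Cell Ranger 3.1.0, bcl2fastq 2.20.0, Seurat 3.4.0 and build mm10, without saying which tool made which file. Trimming settings, read filters, the use of inputs in peak calling and the annotation are not given in the sources used here. Samples were grouped by genotype and kind of library from their titles.

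For bulk RNA, the authors deposited a table of 24974 genes with the mean of log2 values per genotype, the ratio of Ezh1-/- to WT, and a p-value and q-value for each gene. The deposited log2 means are of RPKM plus 0.001, as the lowest values show, so that their powers of 2 are geometric means and differences of low genes are very large. A p-value is lacking for 528 genes. The authors named this table an ANOVA, but the terms of the model behind its p-values are not given in the sources used here. The 6 columns of a further table of RPKM values match no sample's label and were not used. The planned limma fit of single libraries, its replicate block, leaving out a replicate, other splits of the samples and gene list tests with an estimated correlation therefore could not be run, and the deposited p-values took their place. For peaks, the authors deposited 1 list per library with a MACS score for each peak, which is the authors' value and was used only to rank or filter within a list. For single cells, the authors deposited whole UMI counts per gene and barcode.

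The design, gene lists, markers, rule for named genes and 61 alternatives were fixed before the data were examined, and 13 alternatives were added afterwards. Bulk genes with a geometric mean of at least 1 RPKM over both genotypes were kept, and their deposited p-values were adjusted by the Benjamini-Hochberg method at 0.05. The 24 gene lists were tested with cameraPR of limma 3.58.1 in R 4.3.3, two-sided, on signed normal scores of the deposited p-values with a preset correlation of 0.01, in place of the planned camera test. Of these, 23 had at least 5 members in the filtered table. Of the 13 marker lists, 11 had at least 5 members and were tested likewise without a filter. Named bulk genes were 17 fixed genes, the strongest of those passing the adjusted threshold at a mean of at least 5 RPKM without overlap between libraries (0 genes), and up to 4 members of each list with the smallest deposited p. Named single-cell genes were the fixed genes and the 8 highest and 8 lowest ratios of at least 1.5 either way, among genes with at least 200 UMIs and intervals that did not overlap. Of list members, those with the largest differences are also named, as chosen after their values were seen.

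Cells were kept with at least 500 genes and at most 10% mitochondrial UMIs. Both libraries were clustered together with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 components, 15 neighbours, resolution 0.5), without integration. Clusters were named from the fixed markers. A marker counted as present at 0.25 or more of its highest cluster mean and at least 0.5 UMIs per 10000, thresholds set after the clusters were seen, and 2 of 9 clusters stayed unnamed. The doublet caller scrublet marked 0 cells in both libraries and is not taken to have worked, so doublets remain. UMIs of MuSC-like cells were summed per library and given as CPM with exact Poisson intervals, and ratios with exact conditional binomial intervals, all covering counting error only. A list's median was placed among 10000 random lists of equal size matched on mean expression.

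Peak lists were compared with bedtools 2.31.1, an overlap of at least 1 bp counting as shared. The gene table used for positions is of the same build and gives no strand, so peaks were assigned to genes within 2500 bp (H3K27me3) or 1000 bp (ATAC) of either gene end in place of the planned transcription start. Promoter marks were tested against 10027 genes tested in bulk RNA that had a position. The H3K27me3 libraries carry the numbers 1 and 2 in both genotypes, and the labels do not say that a number marks a shared animal or day.

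On simulated data the adjustment step recovered 94.5% of 200 changed genes with 13 false calls among 10139 genes. The gene list test called 95% of lists shifted by 1 unit, and 0% of lists in runs without a shift. Its simulated scores were independent between genes, so false calls in lists whose members move together were not tested. The overlap step found 1200 of 1200 overlaps, and the single-cell sums gave median log2 values of 0.99 and -1.00 for simulated 2-fold changes. The precision of the single-cell values is set by the UMI totals of MuSC-like cells, 12622726 in WT and 14797816 in Ezh1-/-. For the other libraries the number of replicates sets it. Analyses used Python 3.11.15 with scipy 1.17.1 and pandas 2.3.3.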

Results

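Muscle stem cells (MuSCs, the satellite cells that lie beside muscle fibres and rebuild muscle after injury) were sorted from the hindlimbs of wild-type (WT) mice and of mice lacking Ezh1. Ezh1 and Ezh2 are the alternative methyltransferases of Polycomb repressive complex 2, which places the repressive mark H3K27me3 on histone H3. The 18 samples comprised 5 kinds of library. Bulk poly(A) RNA was sequenced from 3 WT and 3 Ezh1-/- samples, H3K27me3 was mapped by chromatin immunoprecipitation (ChIP-seq) in 2 and 2, and open chromatin (ATAC-seq) and single-cell RNA were each measured in 1 and 1. The ChIP inputs, 2 for each genotype, were not analysed here. The single-cell WT library held 3878 barcodes and 16863412 unique molecular identifiers (UMIs), with a median of 4281 UMIs per barcode. The Ezh1-/- library held 3828 barcodes and 17769650 UMIs, with a median of 4629. The depth of the bulk RNA, ATAC and ChIP libraries is unknown. The labels do not state that the samples of a genotype came from separate animals, so p-values measure only the spread between these samples, which may be technical.

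The bulk RNA comparison asked which transcripts differ between MuSCs with and without Ezh1, with the quiescence programme and the Notch pathway as the study's main interest. Ezh1 itself (chromosome 11, 101191115 to 101226463, mm10) fell from a geometric mean of 5.49 RPKM in WT to 0.517 RPKM in Ezh1-/- MuSCs in the authors' deposited table, a log2 difference of -3.41 with an adjusted p of 0.0321. Chst14, a dermatan sulfotransferase, fell by 0.37 on the log2 scale (adjusted p 0.0213) in the authors' deposited table. In the authors' deposited table, Cybc1, a chaperone of the phagocyte oxidase, fell by 0.40 and the centrosomal gene Cdk5rap2 fell by 0.51 (adjusted p 0.0243 for both). Chst14, Cybc1 and Cdk5rap2 were named after their values were seen, since each had a mean below 5 RPKM and the fixed rule for named genes required more, while Ezh1 was fixed beforehand. No gene passed in the higher direction.

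The counts rest on 10139 genes with a mean of at least 1 RPKM. At an unadjusted p under 0.05 in the authors' deposited table, 536 genes were higher and 550 lower in Ezh1-/- MuSCs, where chance alone would give 507 in both directions together. Benjamini-Hochberg adjustment of those p-values left 0 higher and 4 lower. Without the filter 3 were higher and 12 lower, and with a minimum mean of 5 RPKM there were 0 in either direction beside 367 higher and 173 lower at an unadjusted p under 0.05 among 5554 genes. The Y-linked Ddx3y stood at 65.5 RPKM in WT and 0.232 RPKM in Ezh1-/- MuSCs and Xist at 0.0813 and 4.69 RPKM in the authors' deposited table (deposited p 0.116 and 0.154). Such p-values beside such large differences imply a wide spread of these genes between libraries of a genotype, so a genotype may hold both sexes. The sexes of the animals are not given, so a difference of sex, whole or in part, is not separated from genotype in any bulk RNA result below.

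Of the other core Polycomb genes, Ezh2 differed by a log2 of -0.35 (deposited p 0.162), Eed by 0.33 (p 0.209) and Suz12 by 0.10 (p 0.651) in the authors' deposited table. Epop, an accessory subunit of the complex, was 2.02 times its WT level (deposited p 0.0036, adjusted p 0.365) in the authors' deposited table. Pax7, the transcription factor that marks satellite cells (chromosome 4, 139737059 to 139833530), stood at 17.0 RPKM in WT and 9.85 RPKM in Ezh1-/- MuSCs in the authors' deposited table, a log2 of -0.79 with a deposited p of 0.00639 and an adjusted p of 0.365. In the authors' deposited table the myogenic regulators Myf5, Myod1 and Myog differed by 0.31 (p 0.552), 0.21 (p 0.0676) and -0.89 (p 0.202). Among Notch genes, Rbpj, the DNA-binding effector of the pathway (chromosome 5, 53555779 to 53657445), had a log2 of -0.54 (p 0.00346), Notch3 of -0.30 (p 0.0354), Hey1 of -1.03 (p 0.0496) and Hes1 of -0.80 (p 0.0526) in the authors' deposited table. Notch1, Notch2 and Heyl had log2 values of -0.19, -0.36 and -0.38 with deposited p of 0.459, 0.202 and 0.332 in the authors' deposited table. The surface markers Cd34 and Calcr, the calcitonin receptor, had log2 values of 0.61 (p 0.265) and -0.16 (p 0.575) in the authors' deposited table. None of these genes apart from Ezh1 passed the adjusted threshold.

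Gene lists fixed beforehand were then compared with all other genes. Heat shock chaperones fell as a group in Ezh1-/- MuSCs: 16 of 17 members lay below 0, the median log2 was -0.67, and 11 members had a deposited p under 0.05. Among them, in the authors' deposited table, Hspa1a had a log2 of -1.69, Dnajb1 of -1.47, Hsph1 of -1.14 and Hspd1 of -0.67. Cytosolic ribosomal protein genes rose as a group, with 81 of 81 members above 0 and a median of 0.61. Nuclear genes of oxidative phosphorylation rose with 76 of 78 members above 0 and a median of 0.39, and genes of glycolysis rose with 19 of 19 members above 0 and a median of 0.47, including Pgam1 at 0.85 and Hk2 at 0.20 in the authors' deposited table. Extracellular matrix genes rose with 26 of 38 members above 0 and a median of 0.24.

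In the matrix list 8 members were higher and 1 lower at a deposited p under 0.05. The authors' deposited table gave Dcn a log2 of 1.82, Fbln1 of 1.69, Fn1 of 1.35 and Col1a1 of 1.26, while Emilin1 stood at -0.40 (p 0.0127). The adjusted p of limma's competitive test (cameraPR, 23 lists) was 1.32e-09 for heat shock and for ribosomal proteins, 4.43e-06 for oxidative phosphorylation, 0.000157 for glycolysis and 0.00466 for the matrix. The preset correlation of 0.01 treats members as nearly independent. These p-values, and those of the marker lists, are therefore too small where members move together, and the correlation could not be estimated here. With a preset correlation of 0.05 the adjusted p by cameraPR was 5.17e-06 for heat shock, 0.00104 for ribosomal proteins, 0.0143 for oxidative phosphorylation and 0.00723 for glycolysis. Adjusted over the list alone, 11 heat shock genes were lower and 7 matrix genes higher, and no ribosomal, oxidative phosphorylation or glycolysis gene passed. Adjusted over all genes tested, none of these members passed. The call for the matrix was lost with a preset correlation of 0.05 (adjusted p 0.104) and with a minimum mean of 5 RPKM (adjusted p 0.145). Markers of fibroblasts, tendon cells, macrophages and muscle fibres were also higher in the Ezh1-/- bulk RNA, with values given with the marker lists.

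The Notch pathway list had 15 members above and 16 below 0, a median of -0.06 and an adjusted p of 0.340 by cameraPR. Its 3 members with a deposited p under 0.05, Rbpj, Notch3 and Hey1, were all lower. The MuSC quiescence list had 9 members above and 19 below 0, a median of -0.18 and an adjusted p of 0.185. In it, the authors' deposited table gave Fgfr4, a receptor tyrosine kinase, a log2 of -0.67 (p 0.0264) and the syndecan Sdc3 a log2 of 0.49 (p 0.00443). Early response genes had a median of -0.21 and an adjusted p of 0.157, with Maff at -0.86, Egr2 at -0.78, Jun at -0.72 and Dusp1 at 0.46 in the authors' deposited table. All 3 lists were called lower than the other genes when only genes with a mean of at least 5 RPKM were tested, a setting chosen after seeing the data. The adjusted p by cameraPR was then 0.0312 for the Notch pathway, 0.000516 for quiescence and 0.00308 for early response. The test is relative to the other genes, and the median log2 of all genes tested was 0.11 with that filter and 0.02 without it at 1 RPKM. The 33 early response genes and their mean score of -0.45 were the same in both settings. For that list only the comparison genes changed.

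Of the 18 lists not called, the adjusted p by cameraPR ranged from 0.157 to 0.997. It was 0.716 for Notch target genes, Polycomb repressive complex 2, the interferon response, and the TGF beta and BMP pathway. Hox and imprinted genes stood at 0.157, the Wnt pathway at 0.206, other lineage regulators at 0.237, myogenic commitment at 0.264, senescence at 0.340 and mTORC1 with translation initiation at 0.347. Without a filter, also chosen after seeing the data, the Wnt list rose (adjusted p 0.0108), and in it the Wnt inhibitor Wif1 had a log2 of 1.62 in the authors' deposited table. The cell cycle lists stood at 0.789 for G2M and at 0.997 for S phase and for G1 cyclins and inhibitors, and the list of Polycomb repressive complex 1 also stood at 0.997. In the G2M and complex 1 lists the median lay above 0 and the test pointed lower, in the TGF beta list the median lay below 0 and the test pointed higher, and in the G1 list the mean statistic lay above 0 and the test pointed lower.

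**Figure D1:**
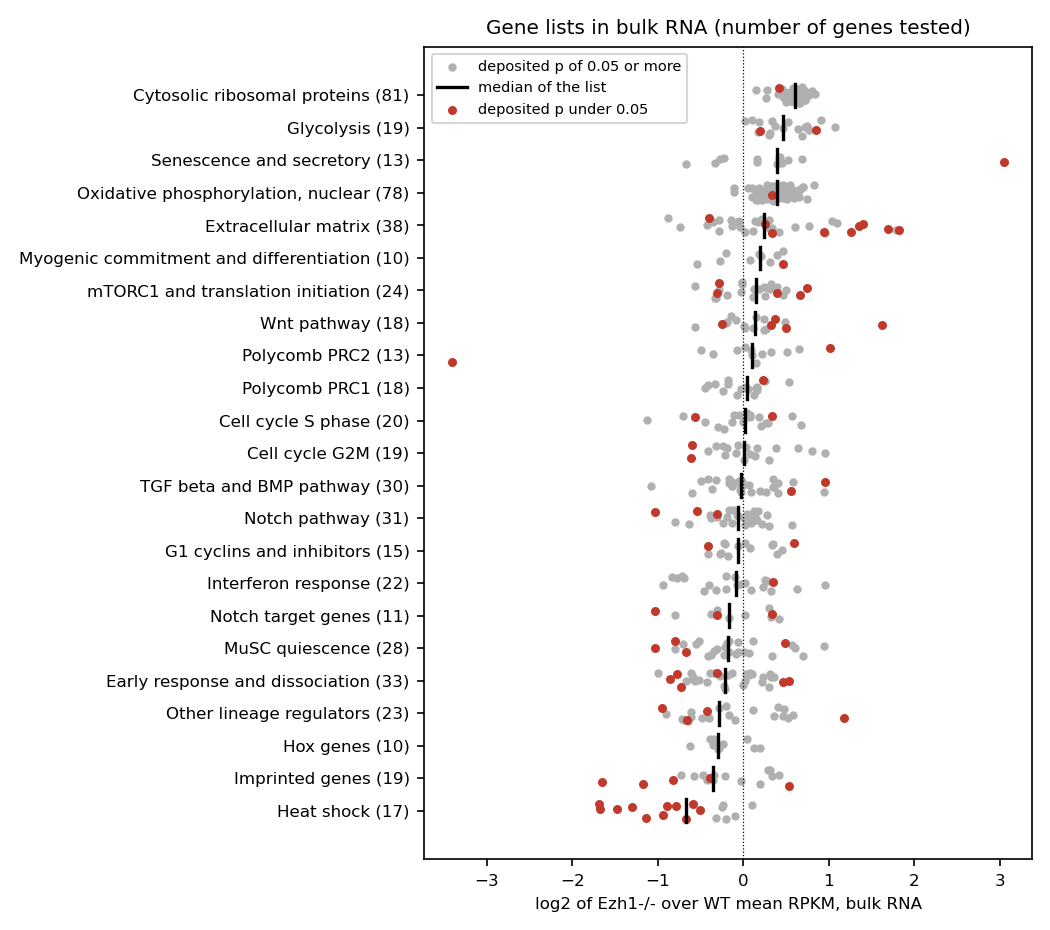
Each point is 1 gene of a list in bulk RNA, placed by its log2 difference between Ezh1-/- and WT geometric mean RPKM from the authors' deposited table, with the list's median as a bar and the number of genes tested in brackets. Ribosomal proteins lie highest at a median of 0.61 and heat shock genes lowest at -0.67, and Ezh1 is the point at -3.41 in the Polycomb list.

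Markers of cell types that the sort could carry along were compared in the same way, with no filter because such markers are low in MuSCs, a choice made after seeing the data. Macrophage and monocyte markers rose in Ezh1-/- bulk RNA, with 8 of 8 members above 0 and a median log2 of 2.86, and in the authors' deposited table Lyz2 had a log2 of 3.48, Tyrobp of 3.12 and Fcer1g of 2.62. Muscle fibre transcripts rose with 9 of 9 above 0 and a median of 2.17, tenocyte markers with 6 of 6 above 0 and a median of 1.38, and fibro-adipogenic markers with 8 of 9 above 0 and a median of 1.26. Glial and endothelial markers rose with medians of 0.77 and 0.72. MuSC markers had a median of -0.16 and did not pass.

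By cameraPR over 11 marker lists, the adjusted p was 1.20e-07 for macrophages, 2.25e-06 for fibro-adipogenic cells, 4.51e-05 for tenocytes and for muscle fibres, 0.00176 for glia and 0.0358 for endothelium, and the call for endothelium was lost with a preset correlation of 0.05 (adjusted p 0.0690). It was 0.209 for MuSCs, 0.169 for pericytes and for cycling cells, 0.149 for lymphocytes and 0.690 for committed myogenic cells. Neutrophil markers (median 4.07) and erythroid markers (median -0.85) had 4 members each and were not tested. The deposited pseudocount of 0.001 RPKM turns small differences of low markers into large log2 values, but over markers with a mean of at least 1 RPKM the medians were 2.79 for macrophages, 2.26 for muscle fibres, 1.56 for tenocytes, 1.17 for fibro-adipogenic cells, 0.72 for endothelium and 0.59 for glia.

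**Figure D2:**
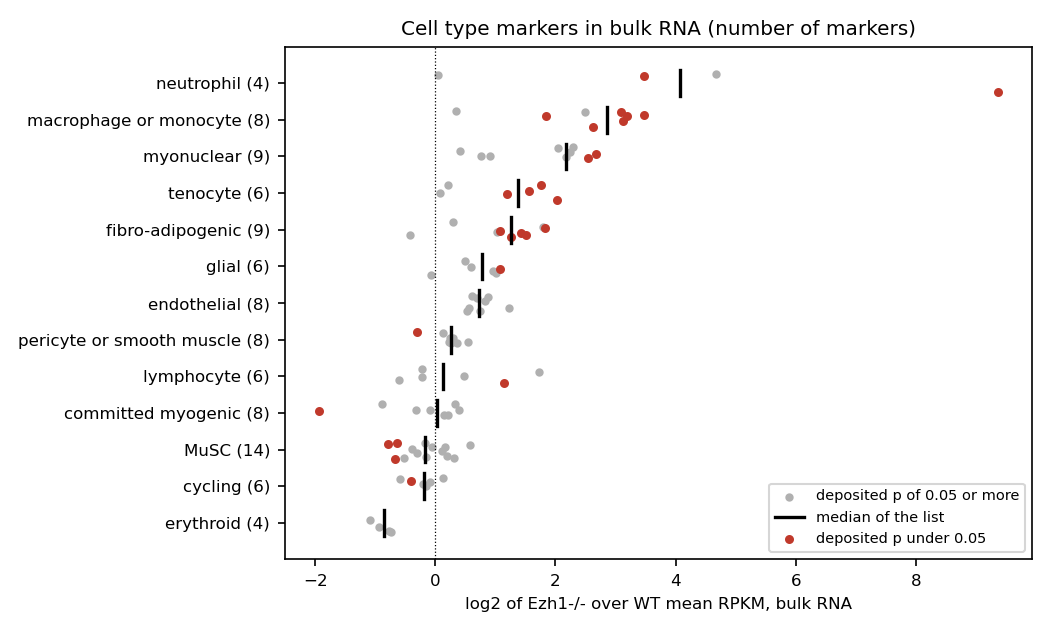
Each point is 1 cell type marker in bulk RNA, placed by its log2 difference between Ezh1-/- and WT geometric mean RPKM from the authors' deposited table, with the list's median as a bar. Macrophage markers have a median of 2.86 and muscle fibre markers of 2.17, while the median of MuSC markers is -0.16.

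Single-cell RNA addressed the same question within cells that carry MuSC markers, with 1 library per genotype and therefore no test. Of 3631 WT and 3534 Ezh1-/- cells kept, 75.8% (95% exact binomial interval 74.4 to 77.2) and 81.9% (80.6 to 83.2) were MuSC-like, in 3 clusters led by genes such as Myod1, Msc, Asb5 and Hmox1. Of these cells, 1689 of 2754 in WT were in cluster 1 and 1441 of 2895 in Ezh1-/- were in cluster 2. With at least 1000 genes per cell and at most 5% mitochondrial UMIs the Ezh1-/- share was 44.1% and the WT share 81.9%, because a cluster with 13 of 13 MuSC markers that held 831 Ezh1-/- and 145 WT cells also carried fibre transcripts and stayed unnamed, so ratios under this filter leave those cells out. Over all clusters in which MuSC markers scored highest, named or not, a count chosen after seeing the data, the shares were 90.9% in WT and 91.3% in Ezh1-/-, with the stricter filter 89.2% and 90.6%, and at resolution 1 87.2% and 85.9%. A cluster that carried MuSC markers together with the fibre transcripts Acta1, Tnnc2 and Ckm stayed unnamed and held 15.04% of WT and 9.34% of Ezh1-/- cells.

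Cluster 5, in which the pericyte markers Kcnj8 and Rgs5 stood beside Cxcl13, C3 and Ccl11, made up 2.31% (1.85 to 2.86) of the WT and 0.651% (0.413 to 0.975) of the Ezh1-/- library, but at resolution 1 the pericyte-like cluster held 1.05% and 0.651%, so the size of this difference is open. Glial-like cells made up 0.909% (0.626 to 1.27) and 1.78% (1.37 to 2.28), and with the stricter cell filter 2.01% and 2.46%. Endothelial-like cells made up 2.42% (1.95 to 2.98) and 2.77% (2.26 to 3.37), and tenocyte-like cells 2.07% (1.63 to 2.58) and 2.49% (2.002 to 3.06), the latter 2.87% and 2.52% with the stricter cell filter. A second unnamed cluster, led by Igkc, Cd74 and Cd79a, held 51 WT and 37 Ezh1-/- cells. The sort before loading sets these shares in part, and all intervals cover counting error only.

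Within MuSC-like cells (2754 WT and 2895 Ezh1-/-), Ezh1 stood at 9.98 CPM (UMIs scaled to a common library total; 95% exact Poisson interval 8.32 to 11.9) in WT and 1.89 CPM (1.26 to 2.73) in Ezh1-/- cells. The deleted part of Ezh1 is not given in the sources used here, so the remaining 3' tags may lie outside it and check nothing. The Notch effector Rbpj stood at 89.4 CPM (84.2 to 94.7) and 47.4 CPM (44.0 to 51.1), and the Notch target Hes1 at 18.9 CPM (16.5 to 21.4) and 8.45 CPM (7.03 to 10.1). Ribosomal protein transcripts together made up 284788 CPM in WT and 371490 CPM in Ezh1-/- cells, and the median log2 ratio of 6181 genes was -0.28. The log2 ratios of fixed genes and of lists are therefore given relative to that median gene, a scale chosen after seeing the data.

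On that scale the log2 ratio was -2.10 (95% interval -2.76 to -1.52) for Ezh1, -0.87 (-1.20 to -0.56) for Hes1 and -0.63 (-0.77 to -0.49) for Rbpj. Myod1 stood at -0.37 (-0.40 to -0.35), Calcr at -0.27 (-0.43 to -0.12), Notch3 at -0.24 (-0.37 to -0.11), Myf5 at -0.18 (-0.23 to -0.13) and Suz12 at -0.17 (-0.32 to -0.02). Notch1 was higher at 0.50 (0.31 to 0.69). The intervals of Pax7 (-0.15, -0.32 to 0.01), Notch2 (0.12, -0.01 to 0.25), Cd34 (0.03, -0.08 to 0.13), Hey1 (0.15, -0.20 to 0.50), Heyl (-0.04, -0.20 to 0.11), Ezh2 (-0.06, -0.32 to 0.19) and Eed (-0.04, -0.25 to 0.18) included 0. On the CPM scale the intervals lay below 0 for Pax7 (-0.61 to -0.27), Notch2 (-0.29 to -0.04), Cd34 (-0.36 to -0.15) and Heyl (-0.48 to -0.17). They also lay below 0 for Ezh2 (-0.61 to -0.09) and Eed (-0.54 to -0.11), while that of Hey1 (-0.49 to 0.22) included 0. Apart from Hey1, whether these genes were lower thus depends on the scale. Relative to the median gene, Ezh2 stood at -0.47, Calcr at -0.56 and Myod1 at -0.14 with the stricter cell filter. At resolution 1 Myod1 stood at -0.56, and over all kept cells Hes1 stood at -0.28. With cells thinned to 2000 UMIs Notch3 stood at -0.41 and Hey1 at 0.64. All these values lay outside the intervals given on the scale of the median gene. Myog had 4 UMIs in WT and 0 in Ezh1-/- cells, too few for a difference to be detectable at this depth.

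**Figure D3:**
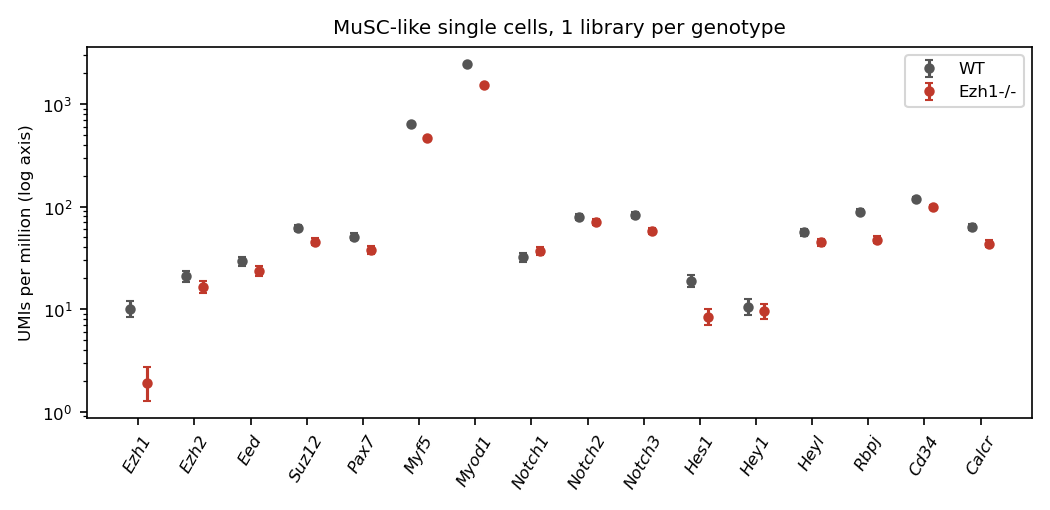
CPM of UMIs summed over MuSC-like cells of the WT and the Ezh1-/- library are plotted on a log axis for the genes fixed beforehand, apart from Myog with 4 and 0 UMIs, and bars are 95% exact Poisson intervals, which cover counting error only. Ezh1 stands at 9.98 and 1.89 and Rbpj at 89.4 and 47.4.

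Among the gene lists, relative to the median gene, ribosomal proteins had a median log2 of 0.62 with 79 of 80 members above 0, above all of 10000 random lists matched on expression. Glycolysis had a median of 0.31 (percentile 99.9 of such lists), with Hk2 at 1.55, and oxidative phosphorylation a median of 0.21 (percentile 100), which was -0.07 on the CPM scale. MuSC quiescence genes had a median of -0.17 with 18 of 26 below 0 (percentile 0.17), among them the thioredoxin inhibitor Txnip at -1.46, the syndecan Sdc4 at -0.93 and M-cadherin (Cdh15) at -0.82, while Rgs2 stood at 0.93. Myogenic commitment genes had a median of -0.36 with 9 of 9 below 0 (percentile 0.02), among them the acetylcholine receptor subunit Chrna1 at -1.07 and Tnnt1 at -1.02. The Notch pathway list had a median of -0.0034 with 10 members on each side (percentile 55.4).

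The matrix list had a median of -0.02 (percentile 44.3), with Bgn at -1.31 and Fbln2 at 1.25. Early response genes had a median of 0.18 (percentile 86.2), which was -0.11 on the CPM scale, with Fos at 0.82, Jun at 0.80 and Egr2 at -1.26. That median was -0.07 over all kept cells, -0.04 at resolution 1, -0.18 with the stricter cell filter and -0.09 with the cluster with fibre transcripts added, so its direction is open. Heat shock genes had a median of 0.05 (percentile 33.6), which was -0.23 on the CPM scale, with Cryab at 2.22 and Hspb1 at -0.88. The heat shock median was -0.34 when the cluster with fibre transcripts, which Dnajb1 also helped to define, was added, -0.33 over all kept cells, -0.32 at resolution 1 and -0.15 with the stricter cell filter. Interferon response genes had a median of -0.19 (percentile 1.38).

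The highest ratios in MuSC-like cells belonged to Gm42047, with 0 UMIs in WT and 234 in Ezh1-/- cells (at least 66.5-fold higher in CPM, against 3 counts over the WT library), and to Npy, the neuropeptide Y gene, with 1 and 269. They were followed by Clmp, an adhesion molecule gene on chromosome 9 (40682123 to 40785553), with 25 and 1184 UMIs and a CPM ratio of 40.4, and by Rab6b, Mpzl2, Nnmt, Gm13373 and Alpl, with CPM ratios of 31.8, 30.01, 12.7, 9.68 and 8.82. At the other end stood Gm47015, with 269 and 2 UMIs, and Dlk1, an imprinted non-canonical Notch ligand gene (chromosome 12, 109452485 to 109463336), with 551 and 14 UMIs. Gm3550, Gm26825, Gm7334, Gm17669, Ccl11 and C1qtnf3 followed with CPM ratios of 0.0447, 0.0643, 0.0653, 0.0984, 0.113 and 0.120. In bulk RNA the authors' deposited table gave Clmp a log2 of -0.24, Npy of -0.43, Nnmt of -1.21 and Dlk1 of 0.10, and C1qtnf3 of -1.001 with a deposited p of 0.0320.

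The H3K27me3 comparison asked whether the mark that Polycomb repressive complex 2 places changes without Ezh1. Hox genes and other developmental regulators, the classical Polycomb targets, carried peaks in both genotypes. Of 39 Hox genes, 0 and 24 had a peak within 2500 bp of a gene end in the WT libraries, against 8 and 23 in the Ezh1-/- libraries. Of 60 other lineage regulators, such as Pax6, Gata6, Lhx1 and Sox2, 1 and 41 had a peak in WT, against 14 and 40 in Ezh1-/-. In library 1 of each genotype the share of all these genes with a peak was lower, at 1.01% in WT and 22.2% in Ezh1-/-, than in library 2, at 65.7% and 63.6%. Of all annotated genes, 0.619% and 3.11% had a peak in the WT libraries and 1.23% and 2.67% in the Ezh1-/- libraries.

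The Notch pathway list of 36 genes had 0 genes with a peak in each of the 4 libraries, and so had the heat shock and matrix lists. Of the genes fixed beforehand, Myod1 (chromosome 7, 46376474 to 46379092) had a peak beside it (46374815 to 46376182) in WT library 2, and the other 16 had none. The Polycomb gene Epop had a peak in Ezh1-/- library 2, and the cell cycle inhibitor gene Cdkn2a had one in library 2 of both genotypes. The widest peaks overlapped in all 4 libraries lay on chromosome 9 (2999996 to 3038512, near Mir101c), at Sfi1 on chromosome 11, and at Hjurp and Mroh2a on chromosome 1. The chromosome 9 and Sfi1 peaks carried the same score of 3100. No filter for regions of artefact signal was applied here, so none of these peaks is read as a Polycomb domain.

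The WT lists held 1683 and 3883 peaks (2783 ± 1556, SD, n = 2) and the Ezh1-/- lists 3840 and 3074 (3457 ± 542, SD, n = 2), a difference smaller than the spread within WT (exact permutation test, two-sided, p = 1, with 0.333 the smallest p possible). They covered 0.315 and 4.33 Mb in WT and 0.937 and 3.06 Mb in Ezh1-/-, with median widths of 121, 828, 166 and 773.5 bp. The Jaccard index of covered bases was 0.262 and 0.239 between genotypes for libraries with the same number, and 0.0287 in WT and 0.0585 in Ezh1-/- between libraries of the same genotype. Overlap between genotypes thus lay above overlap within a genotype for libraries of the same number. The WT lists covered lengths too unlike for their index to reach that of the same-number pairs. These overlaps therefore do not decide whether genotype separates the lists. The log2 ratio of peak numbers was 1.19 for library 1 and -0.34 for library 2.

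**Figure D4:**
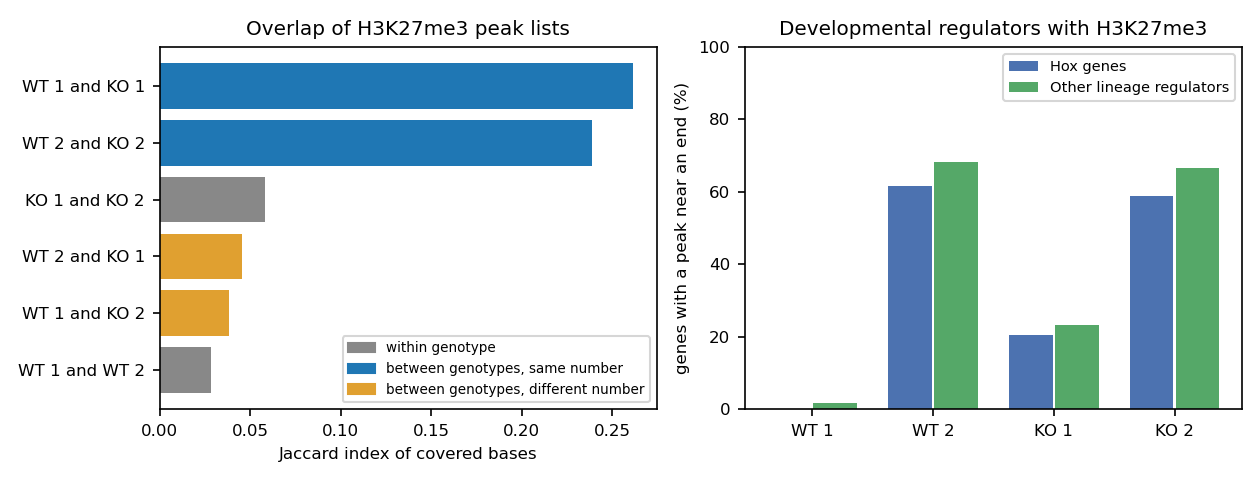
The left panel gives the Jaccard index of covered bases for each pair of the 4 H3K27me3 peak lists, and the right panel the percentage of Hox genes and other lineage regulators with a peak within 2500 bp of a gene end in each library. Pairs with the same number stand at 0.262 and 0.239 and pairs of 1 genotype at 0.0287 and 0.0585.

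The ATAC comparison asked where chromatin is open in each genotype, with 1 library each and no test. Peaks near an end of Pax7, Myf5, Myod1, Notch1, Notch2, Hes1, Hey1, Heyl, Cd34 and Calcr were present in both libraries. Notch3 had 2 peaks (chromosome 17, 32121737 to 32122147 and 32166661 to 32167166) and Myog 1 peak (chromosome 1, 134289547 to 134289867) in the Ezh1-/- library and none in WT, and Rbpj had none in either. Yet the authors' deposited table gave Rbpj 29.6 RPKM in WT and 20.3 RPKM in Ezh1-/- MuSCs. Only peaks within 1000 bp of the listed gene ends were counted, so the promoter of Rbpj in use may lie elsewhere and is not shown to be closed. At Ezh1 the WT library had 2 peaks within 1000 bp of a gene end and the Ezh1-/- library 1, but both WT peaks overlapped a peak of the Ezh1-/- list. Of all annotated genes, 1173 had a peak only in the WT list and 1430 only in the Ezh1-/- list. The Notch ligand gene Dll4, the fusion gene Mymk, the matrix gene Col6a3 and the Hox genes Hoxa2, Hoxb2, Hoxb4 and Hoxb6 also had peaks only in the Ezh1-/- list, and the matrix genes Dcn and Lum and the imprinted genes H19, Snurf and Magel2 only in the WT list.

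The WT list held 77796 peaks with a median width of 669 bp over 64.3 Mb, and the Ezh1-/- list 95743 peaks with a median width of 415 bp over 50.3 Mb. Of these, 85.5% of WT and 74.1% of Ezh1-/- peaks overlapped a peak of the other list, and 24.8% and 22.4% lay within 1000 bp of a gene end. The peak at Pax7 was 2241 bp wide in WT and 608 bp in Ezh1-/-. Narrower and more numerous peaks in 1 library change which genes carry a peak in that library only, and no replicate separates this from genotype.

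Marks near genes were then set beside the bulk RNA. None of the 4 lower genes, Ezh1, Chst14, Cybc1 and Cdk5rap2, had a peak of open chromatin only in Ezh1-/-, or one only in WT, where 6.09% and 3.09% of 10023 other genes had one (Fisher's exact test, two-sided, p = 1 for each), a set too small for a difference to be detectable. With genes at an unadjusted deposited p under 0.05, a set chosen after seeing the data, open chromatin only in Ezh1-/- was found at 45 of 530 higher genes (8.49%, against 5.95% of the others, odds ratio 1.47, Fisher's exact p 0.0244, adjusted p 0.146 over 6 tests) and at 28 of 542 lower genes (5.17%, adjusted p 0.707). The planned tests of H3K27me3 in both WT libraries are not read, since WT library 1 had a peak at 1.01% of the Polycomb targets beside 0.619% of all annotated genes, and they could not show the mark at changed genes. In a further family of 6 tests chosen after seeing the data, H3K27me3 in Ezh1-/- library 2 was found at 17 of 530 higher genes (3.21%, against 1.56%, odds ratio 2.09, Fisher's exact adjusted p 0.0453). The other 5 did not pass: for the higher genes the shares were 1.89% against 1.78% in WT library 2 (adjusted p 1) and 4.15% against 3.14% in any of the 4 libraries (adjusted p 0.405), and for the lower genes the adjusted p was 0.405 in WT library 2 and 1 in the other 2 tests. Fisher's test takes genes as independent, which they are not, and takes each peak list as given. These p-values thus measure no spread between libraries or animals, and Ezh1-/- library 1 was not tested alone. The share in Ezh1-/- library 2 is therefore not read as an effect of genotype.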

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

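The alternatives chosen after the data were seen are the deposited q-values, the common score floor, the scale relative to the median gene, the added cluster, the count of all clusters with MuSC markers highest, the removal of chromosome 9, the gene list settings and the unadjusted gene sets. The bulk count of higher genes was 0 and became 3 without a filter and 6 by deposited q. The count of lower genes was 4 and became 12 without a filter, 0 with at least 5 RPKM, 1 with a 2-fold minimum as well, and 14 by deposited q. None of the 4 lower genes had a mean of at least 5 RPKM, so that filter removed them all. Of genes called in either direction, 6 of 15 without a filter and 8 of 20 by deposited q were listed at 0 in a genotype. There the pseudocount of 0.001 RPKM sets the size of the difference. Other reasons for the change in counts were not tested. The number of gene lists called in bulk RNA, 5, was 4 with a preset correlation of 0.05, 5 with ranks, 6 without a filter and 7 with at least 5 RPKM; the matrix list was lost in the first and last of these, the Wnt list was gained without a filter, and the Notch pathway, quiescence and early response lists were gained with at least 5 RPKM. The log2 ratio of mean H3K27me3 peak numbers, 0.31, ranged from -0.17 to 1.04 when 1 library was left out and was 0.43 with the replicate number as a block. The mean overlap of pairs across genotypes exceeded that of pairs within genotypes by 0.103, which ranged from 0.0838 to 0.125 with a library left out and was 0.131 for equal numbers of peaks; under the block, same-numbered exceeded differently numbered libraries by 0.208. No paired analysis was possible for bulk RNA because its columns carry no sample names, and pseudocounts, scaling, quantile normalization, the variance trend, weights, a left-out replicate, edgeR, the estimated correlation and fry were not run there. The upper 50% of peaks and equal numbers fix the H3K27me3 counts by construction and were left out, and keeping doublets in moved nothing since 0 were marked. The share of WT ATAC peaks overlapping Ezh1-/-, 85.5%, was 91.0% for the upper 50% by score, 79.3% for equal numbers and 70.7% with 50% reciprocal overlap. For Ezh1-/- peaks, 74.1%, these were 76.4%, 83.3% and 57.4%. The promoter mark tests of the 4 lower genes are too small to show that a result holds; that of open chromatin only in WT went from a Fisher's exact p of 1 to 0.0616 with the upper 50% of peaks, and a background of genes with at least 5 RPKM could not give a value because no lower gene passes it. On the CPM scale Hey1, -0.13, was 0.38 in cells thinned to 2000 UMIs and 0.02 with the stricter cell filter. Relative to the median gene, Rbpj was -0.63 in place of -0.91, the Notch pathway median -0.0034 in place of -0.29 and the quiescence median -0.17 in place of -0.45, while Notch2 (0.12), Cd34 (0.028), Hey1 (0.15), oxidative phosphorylation (0.21), early response (0.18) and heat shock (0.05) changed sign; the shift of all ratios by -0.28 is the construction of that scale. The MuSC-like share in WT, 75.8%, was 81.9% with the stricter cell filter and 85.0% at resolution 1, and in Ezh1-/-, 81.9%, it was 44.1% and 71.4%; in both settings a cluster in which MuSC markers scored highest stayed unnamed by the naming rule (831 and 513 Ezh1-/- cells), and over all such clusters, named or not, the main shares were 90.9% in WT and 91.3% in Ezh1-/-.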

Other observations

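Imprinted genes did not pass as a list in bulk RNA (median -0.35, cameraPR adjusted p 0.157), and in MuSC-like single cells 9 of 14 lay below the median gene (median -0.14, percentile 4.9 of random lists), so only single members are given here. In bulk RNA the authors' deposited table gave Mest, a hydrolase gene, a log2 of -1.65 (p 0.00712), the zinc finger gene Peg3 of -0.82 (p 0.0142), Igf2r of -0.38 (p 0.0026) and Igf2 of 0.53 (p 0.0168). In MuSC-like single cells, Dlk1 had 551 UMIs in WT and 14 in Ezh1-/-, and its maternally expressed neighbour Meg3 had 23932 and 9864, a log2 of -1.22 relative to the median gene. Zim1 stood at -1.06, its neighbour Peg3 at -0.54 and Plagl1 at 1.06 on the same scale. In bulk RNA the authors' deposited table gave Meg3 a log2 of -0.58 (p 0.306) and Zim1 of -0.73 (p 0.0784), and gave Dlk1, below 1 RPKM in both genotypes, a log2 of 0.10.

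The sex-linked list did not pass in bulk RNA (5 genes, cameraPR without a filter, adjusted p 0.303). In the authors' deposited table Ddx3y stood at a geometric mean of 65.5 RPKM in WT and 0.232 RPKM in Ezh1-/- (p 0.116), Eif2s3y at 22.9 and 0.0556 RPKM (p 0.121), and Xist, the transcript of the inactive X, at 0.0813 and 4.69 RPKM (p 0.154). In the single-cell libraries Xist had a UMI in 89.0% of WT and 91.4% of Ezh1-/- MuSC-like cells, and Ddx3y in 0 of 2754 and 0 of 2895, which limits the shares of cells with a captured UMI to 0.109% and 0.104% but not the shares that express the gene, and no cell type here gives a background share. Eif2s3y and Uty also had 0 such cells in each library, and Kdm5d had 0 in WT and 1 in Ezh1-/-. These values show no difference of sex between the single-cell libraries. The sexes of the animals are not given in the sources used here, so sex is not separated from genotype in bulk RNA, nor in the comparison of bulk with single-cell RNA. Across 6012 genes in both assays the log2 differences had a Pearson r of 0.257 and a Spearman rho of 0.301, across genes, which are not independent replicates. Of 123 genes with a deposited bulk p under 0.01, 89 (72.4%) had the same sign in single cells relative to the median gene and 67 (54.5%) on the CPM scale.

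All tests of the 3 patterns weighed next were chosen after the result was seen, apart from that of connective tissue RNA. Of the 100 highest ratios in MuSC-like single cells, 19 lay on chromosome 9, among them Clmp, Rab6b, Mpzl2 and Nnmt between 40.7 and 119 Mb, where 5.60 would be proportionate; the next chromosome held 9, and some chromosome held as many in 5 of 10000 random draws. An extra copy of chromosome 9 is argued against, since all its genes lay only 0.0165 (95% bootstrap interval -0.03 to 0.06) above other autosomes. Loss of Ezh1 as the cause is not decided. The 18 of these genes measured in bulk RNA had a median of 1.67 in single cells but of 0.12 in bulk (upper bootstrap bound 0.559). They were picked for high ratios in single cells, and the other 72 of the 100 in bulk also lay lower there (1.28 and 0.42). The gap between the sets in bulk was -0.30 with an interval of -0.55 to 0.20, so the chromosome 9 genes were not set apart. A strain or donor segment on chromosome 9 that differs between these 2 libraries may account for the 19 genes, but of the 100 lowest ratios only 6 lay there, and 5164 of 10000 random draws held at least as many. It stays open, because there is 1 library per genotype and no genotype data were analysed here.

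By Jaccard index the H3K27me3 lists grouped by replicate number and not by genotype. The unlike covered lengths of the WT lists, 0.315 and 4.33 Mb, limit the index of the WT pair whatever the cause. Different score floors are argued against as the cause for the Ezh1-/- pair: with a floor of 50 in all 4 lists its index reached only 0.0730, under the 0.262 of the lower same-number pair. The WT pair stood at 0.0359 with that floor, which decides nothing given its limit. Weaker enrichment at Polycomb targets in both number 1 libraries may account for the grouping: the share of Hox and other lineage regulators with a peak in library 1 was at most 0.349 of that in library 2. Whether a shared day or batch lies behind the numbers was not tested, as the labels give none.

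Extracellular matrix genes were higher in Ezh1-/- bulk RNA while macrophage, tenocyte, fibro-adipogenic and muscle fibre markers were higher too. Dcn, Lum, Col1a1 and Col3a1 belong to both the matrix and the fibro-adipogenic list, so these lists are not separate observations. A smaller share of MuSCs that raises all other cell types alike is not excluded: over markers of at least 1 RPKM the median was 2.79 for macrophages and 0.25 for pericytes, a gap of 2.54 beyond the quartiles of the markers, but with the spread behind the deposited p-values its lower bound was 0.19 by t and -0.11 by normal scores. Erythroid markers went the other way, with a median of -0.76 and a spread of 0.62, but 3 markers were too few to enter this test. RNA of connective tissue cells may contribute, but the 28 members at least 5 times higher in tenocyte-like than in MuSC-like cells had a bulk median only 0.25 (0.246, bootstrap interval -0.11 to 0.83) above the other 10, which decides nothing. Loss of Ezh1 acting within MuSCs stays open as well: the list's median in MuSC-like cells was -0.02 with an upper bound of 0.20, above the 0.12 that would exclude it. That median covers only the 22 members with at least 200 UMIs there. Col1a1, Col1a2, Fn1, Lum and Fbln1, all higher in bulk RNA, had too few UMIs in MuSC-like cells to enter it. These 3 cannot be told apart, because the intervals are wide and single-cell RNA has 1 library per genotype.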
